A study of Homo sapiens with 12 samples.

How the data were processed

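RNA of PANC-1 cells treated with fisetin (80 nM) or DMSO was measured in 12 libraries, 3 in each of 4 groups (fisetin immunoprecipitate, control immunoprecipitate, fisetin input, control input), grouped by the labels. Per the submitters' processing notes, the authors used fastp, HISAT2, HOMER, ChIPseeker, StringTie and edgeR with builds named GRCh38 and hg38; versions are not given in the sources used here. The peak caller, and whether replicates were pooled for it, are not given in the sources used here.

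The deposited tables hold the authors' comparisons only. The transcript table gives, per the file headers, a fold, a log2 fold change, a p-value and an adjusted p (q-value) per Ensembl transcript, fisetin input against control input, all rounded by the authors to 2 decimals. The peak table gives the authors' log2 difference in m6A, a p-value and the log10 of a false discovery rate per region, with the annotated position. The linear fold column was not used. In the deposited table, a total of 10888 log2 cells hold a spreadsheet error. They belong to transcripts marked lower and were read as minus infinity, the counterpart of the 12794 infinite rises. Of the 23682 infinite folds, 522 have a p of 0 and 23160 a p of 1. A p of 1 stands at 65.7% of transcripts. Because p is rounded, ranks among transcripts with a p of 0 rest on the adjusted p and then on size. Regions listed more than once (16 repeats) were counted once. The table has 1715 regions with a p of 0.05 or more, so it is not limited to differential peaks. Its largest p was 0.68, so it may not hold every region that was compared.

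The tables give no counts and no values per library, so depth is unknown, and the planned fits on values per library, leaving out replicates, blocking on the replicate number and rotation or correlation-based list tests were not run. The authors' marks and folds were used instead, which is a departure from the planned test. Gene symbols were given by matching each gene accession in the description column to RefSeq genes (GRCh38.p14) by position, with a span overlap of at least 0.5 (0.9 in a second pass); 22851 of 24498 genes (93.3%) received a symbol. No RefSeq coordinates are printed.

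A gene's fold is the median over its transcripts with a finite fold and a p under 1 (44746 transcripts, median 0.10). Each transcript counts alike whatever its level, so this gene median is not the change in total RNA of the gene. The gene lists (32, fixed before the data were examined) cover m6A enzymes, DNA repair, cell cycle, stress, metabolism, inflammation, chromatin, ribosomes and mitochondria, and markers of ductal, acinar, endocrine, fibroblast and leukocyte cells. For lists with at least 5 measured genes, the list median was compared with 10000 random lists of the same size, matched on the number of transcripts per gene (two-sided, Benjamini-Hochberg over 29 lists; 0.000725 is the smallest adjusted p these draws gave). The random range is the central 95% of those lists. The number of marked transcripts was compared with random placement over transcripts with a p under 1 (hypergeometric, one-sided, Benjamini-Hochberg), which treats isoforms of a gene as independent. Counts adjusted over the list alone use the deposited, rounded p; with each p at the upper end of its rounding interval, 0 transcripts pass in every list. Peak tests were an exact binomial test, Fisher's exact test and, for m6A against RNA level, a permutation test with 100000 resamples. Exact binomial intervals cover counting error only.

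Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls at an adjusted p under 0.05, up to 4 members of each described list by smallest p, 8 higher and 8 lower peaks by smallest p with ties by size, up to 2 peaks per list, and ZC3H13, PHF10, METTL3, METTL14, FTO and ALKBH5 in any case. The condition that replicates do not overlap could not be applied, and a finite fold was required instead. HK2, set side by side in both tables, was chosen after its values were seen. Some members that the rule names are not reported here.

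The resampling tests were tested on simulated data made from the real values. With lists of 25 genes among 13434, the list test called 4.0% of unshifted lists at an unadjusted p under 0.05, 40.5% of lists shifted by 0.25 log2 and 96.5% of lists shifted by 0.5. The m6A against RNA test, at 937 and 662 genes, called 3.5% of comparisons without a difference and 100.0% of those with 0.2. The test of directions within genes, at 1501 genes, called 3.0% of shuffled sets, and the stratified odds ratio, at 2415 peaks, called 3.5% of sets without an effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.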

Results

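The series profiled N6-methyladenosine (m6A), the most common internal mark of messenger RNA, in PANC-1 cells, an established human pancreatic ductal adenocarcinoma line. Cells received fisetin, a plant flavonol, at 80 nM, or its solvent DMSO. RNA bound by an m6A antibody (the immunoprecipitate) and RNA set aside before binding (the input) were sequenced from 3 fisetin and 3 control samples each, 12 libraries in all. The input libraries measure RNA level, and the immunoprecipitate set against the input measures m6A. The analysed tables hold the authors' own comparisons of fisetin with control, 131819 transcripts for the input and 4130 distinct regions for m6A, without values per library. Sequencing depth and the spread between replicates are therefore unknown, and no replicate error can be printed beside a fold change. The design text of the series calls the replicates matched without saying by what, and the labels carry replicate numbers only. The p-values of the tables may measure technical spread only.

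The first comparison asked which RNAs differed in level between fisetin and control input. Individual transcripts rose and fell in similar numbers: 1846 of the 131819 transcripts were marked significant in the authors' deposited table, 965 higher and 881 lower with fisetin. They belonged to 1501 genes, of which 732 had only higher, 639 only lower and 130 both kinds of marked transcript. Genes with only higher marks were 53.4% of the 1371 with marks in 1 direction (exact binomial test over genes against 50%, two-sided p = 0.0129). Since 56.1% of all 13434 measured genes had a median transcript fold above 0, this is no excess of rises over the general offset of the table. The mark follows an unadjusted p, and 616 transcripts had an adjusted p under 0.05 in the authors' deposited table, 342 higher and 274 lower. Only 191 of these 616 had a finite fold, so most of the stricter set are infinite folds. For 522 of the marked transcripts the fold was infinite, as it is when the level in 1 condition is listed at 0.

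The largest finite rises at an adjusted p under 0.05 in the authors' deposited table were SYCP2, a synaptonemal complex protein of meiosis, at a log2 fold change of 25.02, LIN54, a DNA-binding subunit of the DREAM cell cycle complex, at 18.71, and SLC25A6, a mitochondrial ADP/ATP carrier, at 15.30. The same table listed RWDD4 at 14.26, NEDD4L, a ubiquitin ligase, at 14.10, SLC38A7, an amino acid transporter, at 14.05, ACVR1, an activin and BMP receptor, at 12.67, TRNT1, which adds CCA ends to tRNAs, at 12.50, and EHBP1 at 12.01. The largest falls in the authors' deposited table were ASB3 at -16.80, SHTN1 at -15.02, RPL14, a ribosomal protein, at -14.07, ACBD5, a peroxisomal tether, at -14.02 and OGDH, an enzyme of the citric acid cycle, at -13.87. SYPL1 followed at -13.32, SRP72, of the signal recognition particle, at -13.07, RNF4, a SUMO-targeted ubiquitin ligase, at -12.89 and SPNS1 at -12.13 in the authors' deposited table. CSNK2A1, the catalytic subunit of casein kinase 2, was in both groups: its transcript ENST00000645840 stood at 12.32 and ENST00000645910 at -14.16 in the authors' deposited table. Each of these values belongs to a single transcript model, not to the whole gene. For RPL14 the gene median was 0.205 over 6 transcripts. Gene medians here and below count each transcript alike whatever its level, and are no gene totals. Levels per condition are unknown, so how near 0 the lower level lay cannot be told. These folds are therefore no measure of effect size. The SYCP2 model ENST00000371001 lies on chromosome 20 from 59863564 to 59932154 (GRCh38) and has 44 exons.

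Lists of DNA repair genes were fixed because the study is understood to bear on homologous recombination repair. Genes of homologous recombination, which repairs double-strand breaks from a sister copy, lay higher with fisetin as a group. Of 36 measured members 34 had a median transcript fold above 0, against 56.1% of all 13434 measured genes, and their median log2 fold change was 0.57 against a random range of -0.11 to 0.32 (adjusted p = 0.000725). Among the members with the smallest p in the authors' deposited table were BRCA1, with marked transcripts of infinite fold, and RAD51AP1, a recombination accessory factor, at a log2 fold change of 4.32. EME1, a nuclease subunit, stood at 2.81 there with a p of 0.05 and no mark. Marked transcripts were no more frequent in the list than elsewhere (5 higher and 0 lower, 6.12 expected), and 3 passed an adjusted p under 0.05 over all transcripts and 3 adjusted over the list alone. For this and every later list, a p rounded to 0 always passes the adjustment over the list alone. With each p at the upper end of its rounding interval, 0 transcripts pass in every list. Counts adjusted over the list alone therefore reflect the rounding and lend a list no support. DNA damage checkpoint genes also lay higher, with a median of 0.51 over 21 genes and 15 members above 0 (adjusted p = 0.0248). Their marked transcripts were 5 higher and 1 lower. In the authors' deposited table a transcript of CHEK1, the kinase that halts cells with damaged DNA, stood at 5.12, one of the phosphatase CDC25B at 3.98, and ATRIP, the partner of the kinase ATR, had an infinite rise. Over its 9 transcripts the gene median of CHEK1 was -0.05. RAD17, a clamp loader, had 1 marked transcript in each direction. None of the checkpoint transcripts passed adjustment over all transcripts, and 2 did adjusted over the list alone. The checkpoint call was lost when every finite transcript was used (adjusted p = 0.213). Genes of non-homologous end joining had a median of 0.24 and p53 targets one of 0.19, neither apart from random lists (adjusted p = 0.586 and 0.655).

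The stress response, NF-kappaB, immediate early and NRF2 lists lay higher, while the heat shock and interferon lists below did not. The integrated stress and unfolded protein response, with which cells meet amino acid shortage and misfolded protein, had a median log2 fold change of 0.68 over 29 genes, 26 of them above 0 (random range -0.17 to 0.33, adjusted p = 0.000725). Its members carried 13 higher and 1 lower marked transcripts where 4.21 were expected (adjusted p = 0.00239). The 4 members of smallest p in the authors' deposited table were SHMT2 and PHGDH, enzymes of serine and glycine metabolism, each with an infinite rise, MANF, a secreted endoplasmic reticulum protein, at 7.52, and CRELD2, whose marked transcript had an infinite fall. By gene 8 members had only higher and 1 only lower marks, a split not apart from that of other genes (Fisher's exact test, adjusted p = 0.302). The gene medians of MANF and CRELD2 were 0.16 and -0.02, and those of SHMT2 and PHGDH 0.68 and 1.30. Over all transcripts 3 passed adjustment, and 5 adjusted over the list alone. NF-kappaB targets had the highest list median, 0.79 over 20 genes with 18 above 0 (adjusted p = 0.000725). Among them CXCL8, the chemokine interleukin-8, stood at 4.19 and TRAF1, a TNF receptor adaptor, at 6.69 in the authors' deposited table, while 1 transcript of TNFAIP2 stood at -2.05 and PTGS2, cyclooxygenase 2, at 2.46 without a mark. The gene median of TNFAIP2 was 0.41 over 4 transcripts. No NF-kappaB transcript passed adjustment over all transcripts or adjusted over the list alone. Immediate early genes had a median of 0.51 over 27 genes (adjusted p = 0.0232). DUSP5, a phosphatase of ERK, stood at 3.23 and the stress factor ATF3 at 3.65, against -4.85 for 1 transcript of MYC and an unmarked 2.14 for FOSL1, in the authors' deposited table. The gene median of MYC was -0.20 over 4 transcripts. Their call was lost with every finite transcript (adjusted p = 0.161), and 0 transcripts passed adjustment over all and 1 adjusted over the list alone. Targets of NRF2, the regulator of antioxidant genes, had a median of 0.47 over 25 genes (adjusted p = 0.0277). HMOX1, heme oxygenase 1, stood at 2.29 and SLC7A11, the cystine importer, at 2.37, and 1 transcript of FTH1, a ferritin chain, had an infinite rise in the authors' deposited table, against a gene median of 0.005. For NRF2 targets 2 transcripts passed adjustment over all and 2 adjusted over the list alone.

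Apoptosis genes held 9 higher and 3 lower marked transcripts where 3.96 were expected (adjusted p = 0.00907), although the list median of 0.22 was not apart from random lists (adjusted p = 0.504). With means of genes in place of medians it was 0.84 and passed (adjusted p = 0.000725), a mean that leaned on CYCS and BCL2L2 and fell to 0.37 without them. In the authors' deposited table CYCS, cytochrome c, stood at 10.24, BCL2L1, which encodes the survival protein BCL-XL, at 8.52, DIABLO, an antagonist of caspase inhibitors, had an infinite rise and BCL2L11, the killer protein BIM, an infinite fall. These are values of single transcripts: the gene medians were 8.74 for CYCS but 0.06 for BCL2L1, -0.10 for DIABLO and -0.55 for BCL2L11. The CYCS median is the middle of 3 transcript models, among them those marked at 10.24 and 8.74. It does not measure the total RNA of the gene. By gene 7 members had only higher and 3 only lower marks (Fisher's exact test against other genes, adjusted p = 0.676). The named members include genes that promote and genes that oppose cell death. Over all transcripts 6 passed adjustment, and 7 adjusted over the list alone.

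Lists of glycolysis and hypoxia, cholesterol, fibroblast, ductal and epithelial-mesenchymal genes lay lower. Glycolysis and hypoxia genes had a median log2 fold change of -0.42 over 30 genes, 24 of them below 0 (random range -0.12 to 0.34, adjusted p = 0.000725). The smallest p in the authors' deposited table belonged to PKM, pyruvate kinase, with an infinite fall, PFKFB3, a glycolytic regulator, with an infinite rise, GPI at -8.75 and ALDOC, an aldolase, at -3.90. Their gene medians, in this order, were -0.28, -0.89, -1.03 and -2.92. The list's marks were 6 higher and 4 lower, so the marked transcripts did not follow the direction of the list, and 4 transcripts passed adjustment over all and 7 adjusted over the list alone. Cholesterol biosynthesis genes had a median of -0.34 over 23 genes, 18 below 0 (adjusted p = 0.00539). A transcript of SC5D, a late enzyme of the pathway, stood at 7.85 and was its only mark in the authors' deposited table, in which LSS, lanosterol synthase, stood at an unmarked -1.74. The SC5D transcript was also the 1 that passed adjustment, over all and adjusted over the list alone, and the gene median of SC5D was 0.27. Fibroblast and stellate markers had a median of -1.06 over 8 genes (adjusted p = 0.00232). The collagen genes COL1A1 and COL3A1 stood at -2.26 and -1.84, FBLN1 at -3.87, and THY1 had an infinite rise in the authors' deposited table; 1 transcript passed adjustment over all and 1 adjusted over the list alone. The FBLN1 value is that of 1 transcript, with a gene median of -0.31 over 8, and the gene median of THY1 was 0.20. Ductal epithelial markers had a median of -0.95 over 7 genes (adjusted p = 0.00532), and this call was lost with every finite transcript (adjusted p = 0.0934). KRT18, an epithelial keratin, stood at -4.56 in 1 transcript, SPP1 had an infinite rise, and KRT8 at -2.34 and the duct factor SOX9 at -3.40 were unmarked in the authors' deposited table. Another KRT18 transcript was marked at 2.37 in the authors' deposited table, and its gene median was -0.18. The KRT8 value belongs to 1 transcript, and the gene median of KRT8 was 0.67 over 8 transcripts, the 1 ductal gene above 0. The ductal marks were 2 higher and 1 lower, against the direction of the list. The epithelial-mesenchymal list, which mixes markers of both states, had a median of -0.30 over 24 genes (adjusted p = 0.0270). KRT8, KRT18, KRT19, EPCAM and CLDN4 are in both this and the ductal list, so their falls are not separate results. The epithelial-mesenchymal call was not stable. This list lost the call with every finite transcript and with means of genes (adjusted p = 0.307 and 0.125). A transcript of CTNNB1, beta-catenin, stood at -2.21, FN1, fibronectin, had an infinite rise and CLDN1, a tight junction protein, stood at an unmarked 2.29 in the authors' deposited table. The gene medians of CTNNB1 and FN1 were -0.23 and -0.96. In the epithelial-mesenchymal and in the ductal list 2 and 1 transcripts passed adjustment over all, and 2 and 2 adjusted over the list alone. The KRT18 transcript at -4.56 was counted in both lists.

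**Figure D1:**
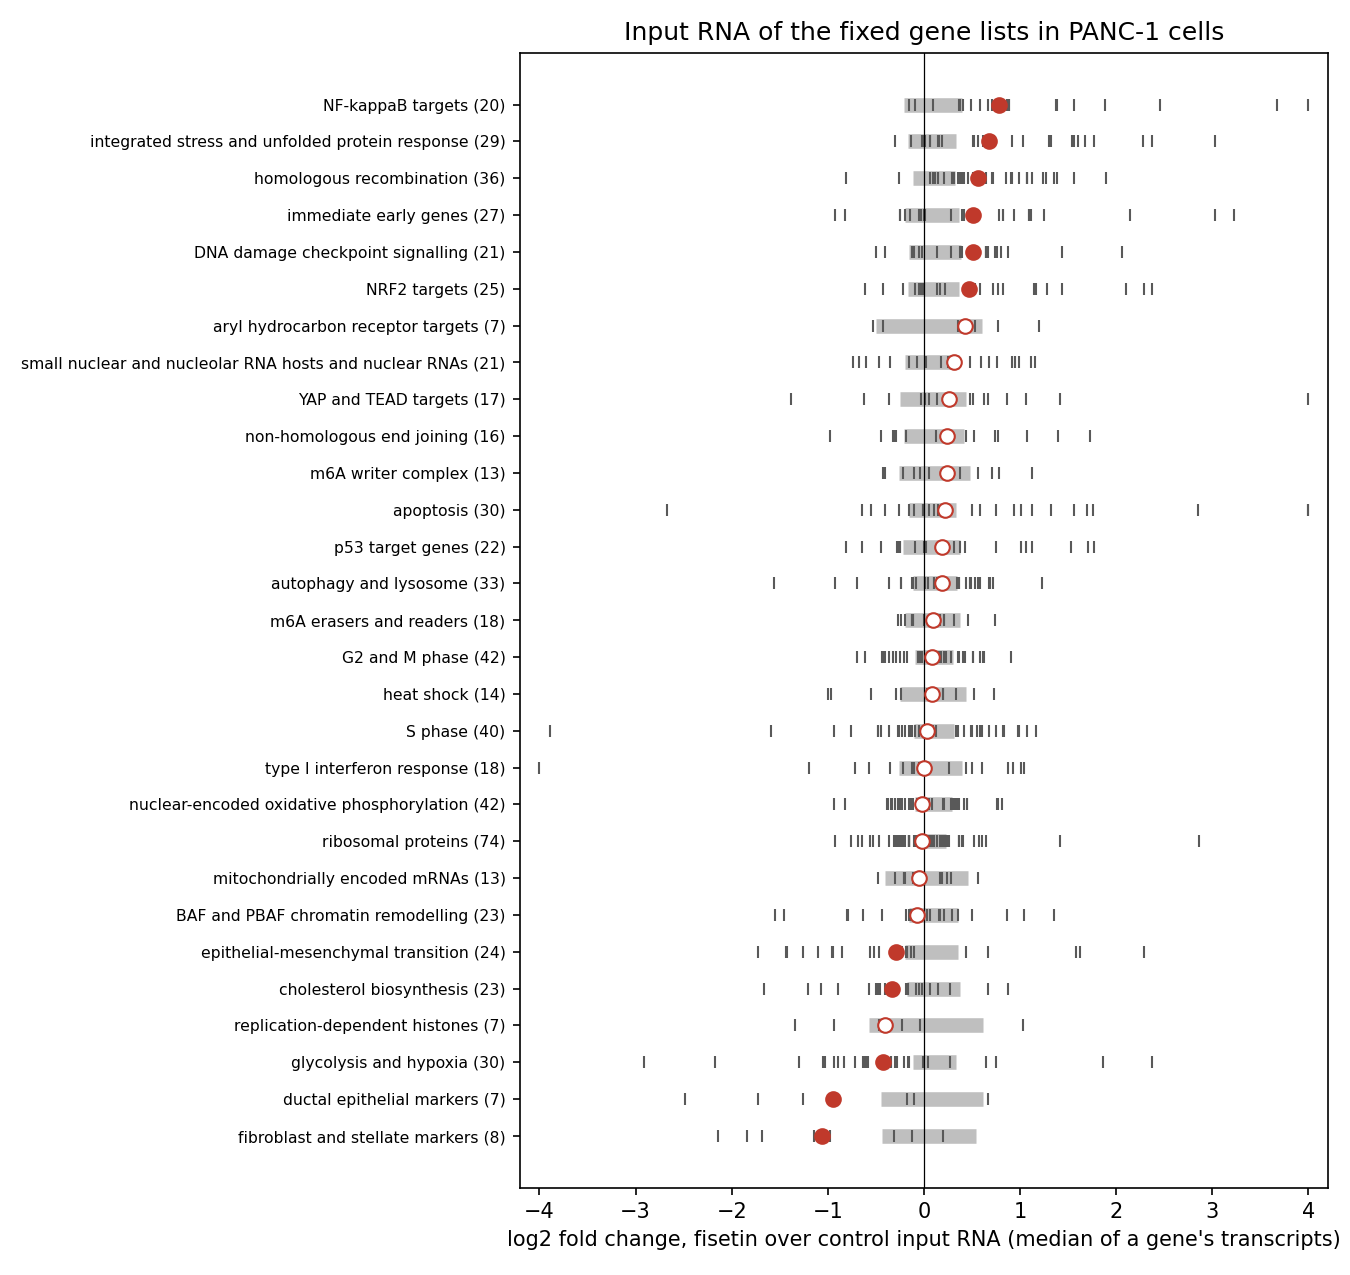
Log2 fold change of input RNA, fisetin over control (x axis), for each gene list with at least 5 measured genes (y axis, number of genes in brackets). Ticks are genes (the median of a gene's transcripts, drawn at the edge beyond 4), circles are list medians, filled at an adjusted p under 0.05, and grey bars span 95% of random lists; NF-kappaB targets lie highest at 0.79 and fibroblast markers lowest at -1.06.

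Cell cycle lists did not stand apart from random lists, with medians of 0.04 for S phase and 0.09 for G2 and M phase (adjusted p = 0.667 and 0.932). The same held for ribosomal proteins at -0.02, nuclear-encoded oxidative phosphorylation at -0.02 and mitochondrially encoded mRNAs at -0.05 (adjusted p = 0.140, 0.343 and 0.788). Heat shock genes had a median of 0.09, autophagy and lysosome genes 0.19, YAP and TEAD targets 0.27 and RNA hosts and nuclear RNAs 0.31 (adjusted p = 0.980, 0.696, 0.504 and 0.276). The YAP and TEAD list passed with means of genes (0.56, adjusted p = 0.0398), which rested on ANKRD1 (0.23 without it), and the RNA hosts with transcripts of at least 1000 bases (0.62, adjusted p = 0.0218). Aryl hydrocarbon receptor targets, which flavonoids can induce, had a median of 0.43 over 7 genes (adjusted p = 0.343), type I interferon genes one of 0 and replication-dependent histones one of -0.40 (adjusted p = 0.756 and 0.276). Acinar, endocrine and leukocyte markers had 0, 2 and 3 genes with a p under 1 in the authors' deposited table and were not tested. For every list these p-values come from random lists of genes, which are not independent replicates and were not matched on expression, so genes regulated together make them too small.

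Enzymes that write, erase and read m6A did not stand apart as groups: the writer list had a median of 0.24 over 13 genes and the erasers and readers 0.09 over 18 (adjusted p = 0.655 and 0.992). The writer list holds METTL16, METTL5, TRMT112, ZCCHC4 and PCIF1 beside subunits of the writer complex. Its median is therefore not that of the complex. ZC3H13, a subunit of the writer complex, had no marked transcript; its full-length models ENST00000242848 and ENST00000282007 stood at -0.23 (p = 0.74) and 0.14 (p = 0.97) in the authors' deposited table. The catalytic subunit METTL3 was likewise unmarked, with its model ENST00000298717 at 0.24 (p = 0.95), as was its partner METTL14, with ENST00000388822 at -0.25 (p = 0.77), in the authors' deposited table. The demethylase ALKBH5 stood at -0.12 (p = 0.81, ENST00000399138), and 1 transcript of the demethylase FTO, ENST00000637001, had a marked infinite rise with an adjusted p of 0.07 in the authors' deposited table. METTL5, which methylates ribosomal RNA, and LRPPRC, among the readers, each had 1 transcript of infinite rise there. The gene median of METTL5 was 0.24 over 8 transcripts and that of LRPPRC -0.27 over 4. Among the readers FMR1 had a transcript marked higher at 5.16 and HNRNPA2B1 one marked lower at -2.35 in the authors' deposited table, with gene medians of 0.17 and -0.11.

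PHF10, a subunit of the PBAF chromatin remodelling complex, had lower transcripts with fisetin. It lies on chromosome 6, and 3 of its 6 transcripts were marked lower in the authors' deposited table. ENST00000339209, from 169703902 to 169724500 with 12 exons, stood at a log2 fold change of -1.33 (p = 0.00 as rounded, adjusted p = 0.03), and ENST00000480008 and ENST00000621772 had infinite falls in the authors' deposited table. The other 3 models stood at -0.63 (p = 0.44), 0.80 (p = 0.56) and -0.80 (p = 1) in the authors' deposited table. The p of ENST00000339209 lay outside the relation of p to fold seen in the other transcripts. Among 2779 further transcripts with an absolute log2 fold change within 0.15 of 1.33 the smallest p was 0.09, and no other finite fold under 1.78 was marked in the authors' deposited table. BAF and PBAF genes as a list carried 5 higher and 8 lower marked transcripts where 5.70 were expected (adjusted p = 0.0445), and 3 of the lower ones were those of PHF10. SMARCA4, the ATPase of the complex, had 1 transcript of infinite fall and ARID1B 1 of infinite rise in the authors' deposited table. SMARCE1 had 1 transcript of infinite rise and 1 marked lower at -8.77 in the authors' deposited table. The gene medians of SMARCA4, ARID1B and SMARCE1 were 0.06, -0.19 and 0.21. The list median of -0.07 was not apart from random lists (adjusted p = 0.343), and 7 transcripts passed adjustment over all and 9 adjusted over the list alone.

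**Figure D2:**
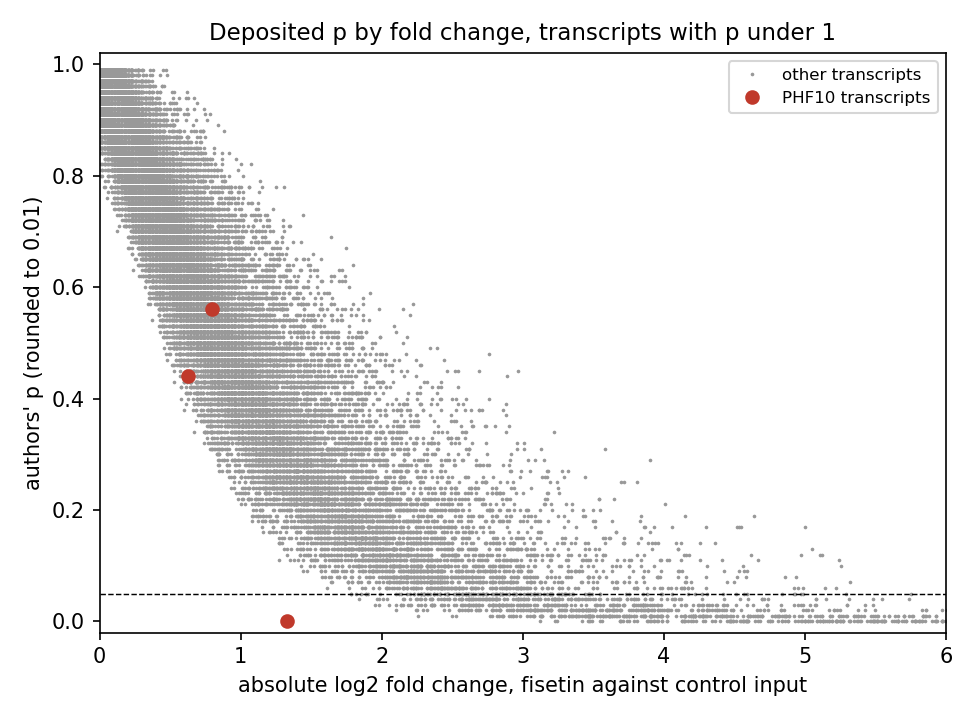
The authors' p (y axis) against the absolute log2 fold change of input RNA (x axis, shown to 6) for finite transcripts with a p under 1; each point is a transcript, red points are PHF10, and the dashed line marks 0.05. The red point at 1.33 lies below the band of the other transcripts, whose smallest p near that fold is 0.09.

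The second comparison asked which m6A peaks differed. Of 4130 regions, 2415 had a p under 0.05 in the authors' deposited table, and more of them were higher (1381) than lower (1034) with fisetin. The largest p listed was 0.68 and the smallest absolute log2 difference 0.1, so regions that differed least may be missing. The 2415 are therefore no measure of the share of all m6A peaks that differed. Counting 1 peak per gene, 1076 of 1862 genes were higher, or 57.8% (exact 95% interval 55.5 to 60.0, exact binomial test, two-sided p = 1.94e-11). Genes share the same libraries and are not replicates, so this p and interval do not measure the spread between replicates. At a false discovery rate under 0.05 there were 1824 peaks, 1031 higher and 793 lower, in the authors' deposited table. Typical differences were modest, with a median log2 difference of 0.82 among higher and -0.68 among lower peaks.

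Higher peaks lay more often in 3' UTRs. Of the 3' UTR peaks 67.4% were higher (791 of 1174), of the 5' UTR peaks 52.0% (333 of 640) and of the other exon peaks 42.8% (257 of 601). The odds ratio of 3' UTR against all other positions was 2.28 (Fisher's exact test, two-sided p = 5.85e-23). It was 3.27 (95% interval 2.52 to 4.25) among regions up to 500 bases and 1.34 (1.06 to 1.68) among longer ones. Higher regions also had shorter genomic spans, introns included, with a median of 359 bases against 870 for lower ones. These tests count peaks, which are not replicates.

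**Figure D3:**
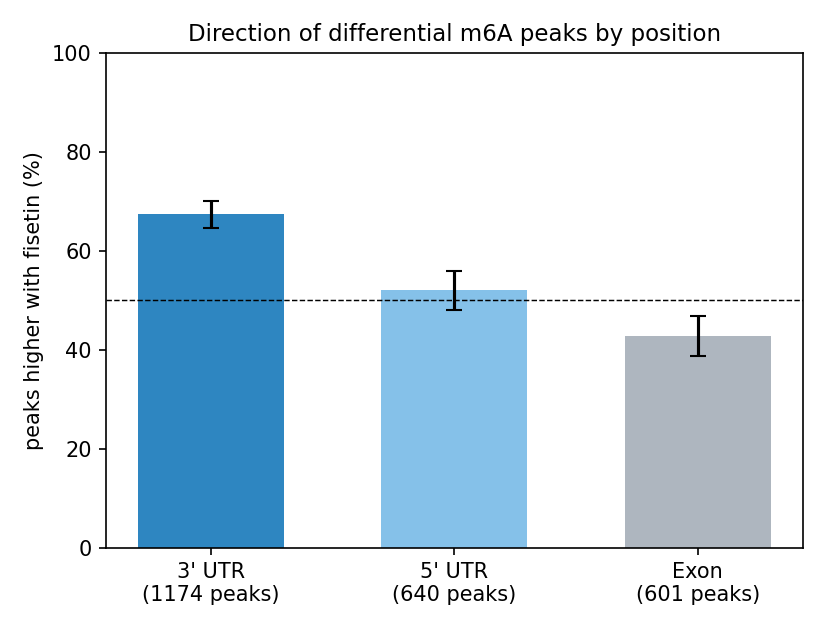
Percent of differential m6A peaks (p under 0.05) that were higher with fisetin (y axis) by annotated position (x axis, number of peaks in brackets). Bars are shares, error bars exact 95% binomial intervals over peaks, and the dashed line marks 50%; the 3' UTR bar stands at 67.4%, the exon bar at 42.8%.

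By the ranking on p and then on size, the first of the higher peaks in the authors' deposited table was a region annotated as the 5' UTR of WDR74 (chromosome 11, 62841646 to 62841809) at a log2 difference of 6.11. Whether another gene overlaps that region was not checked. RPL21P119, a ribosomal protein pseudogene, followed at 4.92, the 3' UTR of MALL at 4.89, CACNA1D, a calcium channel, at 4.78, NPAS2, a clock factor, at 4.53, NR2E3 at 4.45, KAT6A, a histone acetyltransferase, at 3.91 and NDUFV3, of respiratory complex I, at 3.91 in the authors' deposited table. The first of the lower peaks was in the 3' UTR of BOC (chromosome 3, 113251385 to 113251595) at -5.42 in the authors' deposited table. It was followed there by IKBKG, a regulator of NF-kappaB, at -5.21, BOLA2 at -5.19, FAM156B at -5.11, HSFX2 at -4.52, TAS2R5, a taste receptor, at -4.34, OCLNP1, a pseudogene, at -4.06 and NMNAT3, an enzyme of NAD synthesis, at -4.06. IKBKG, BOLA2, FAM156B, HSFX2 and both pseudogenes have near-identical copies elsewhere in the genome, so that reads could be split between copies.

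Ribosomal protein genes had higher m6A in all 10 genes with a differential peak, with a median log2 difference of 0.65 (Fisher's exact test against other genes, p = 0.00675, adjusted p = 0.0540, which misses 0.05). The peak counted for each of these 10 genes lay in a 3' UTR. With 1 peak per gene, 68.2% of all 3' UTR peaks were higher. The test took other genes at every position, so it cannot separate the list from that position. The 3' UTR peaks of RPL34 and RPS7 stood at 1.13 and 1.0 in the authors' deposited table. S phase genes were higher in 5 of 5, among them PRIM2 at 0.65 and CDC6 at 0.61 in the authors' deposited table (adjusted p = 0.317). Homologous recombination genes split 4 higher to 2 lower (adjusted p = 1), with RAD51C at 1.45 and EME1 at -0.61, and checkpoint genes 1 to 4 (adjusted p = 0.447), with CDC25A at 0.88 and RAD9A at -0.81, in the authors' deposited table. Apoptosis genes split 3 to 3, epithelial-mesenchymal genes 4 to 3, glycolysis and hypoxia genes 2 to 3 and immediate early genes 4 to 1 (adjusted p = 0.932, 1, 0.932 and 0.815). CCN2, a matricellular growth factor, stood at 1.08 and CEBPB, a stress-response factor, at 1.32 in the authors' deposited table.

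PHF10 had 2 regions of opposite direction assigned to it, both annotated as 5' UTR on chromosome 6. No PHF10 transcript model reached past 169725566, so the second of them, 13294 bases long, lies almost wholly beyond the gene's models. The region from 169724108 to 169725566 stood at a log2 difference of -1.53 and the region from 169725504 to 169738797 at 2.43, both with a p of 0.01 in the authors' deposited table. That p does not match their false discovery rates of 0.195 and 0.263 in the authors' deposited table. The other 366 regions with a p of 0.01 had false discovery rates of 0.0229 to 0.0562, and other regions near 0.195 and 0.263 had a p of 0.08 and 0.12 in the authors' deposited table. By false discovery rate neither PHF10 region is differential, though both are among the 2415 counted by p. No region of that table carried the name ZC3H13, METTL3, METTL14, FTO or ALKBH5.

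The third comparison set m6A against RNA level. Genes with only higher peaks had a mean input log2 fold change of 0.10 (937 genes) and genes with only lower peaks one of 0.01 (662 genes). The difference of 0.09 (SE 0.04 over genes) passed narrowly (permutation test, two-sided p = 0.0466). By the same permutation test it turned to -0.06 (p = 0.548) among peaks with an absolute log2 difference of at least 1 and missed 0.05 with every finite transcript (p = 0.123). Of 183 genes with marked transcripts in 1 direction and differential peaks in 1 direction, 60 were higher in both, 59 higher in m6A and lower in RNA, 38 lower in m6A and higher in RNA and 26 lower in both (Fisher's exact test, two-sided p = 0.278). In the authors' deposited tables HK2, hexokinase 2, was higher in both (1.10 for m6A, 4.43 for RNA), the RNA value being that of 1 of 2 transcripts. Both measures use the same input libraries and share their error, and genes are not replicates.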

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

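The planned limits on fold and false discovery rate were set before the data were examined; the use of adjusted p, finite folds, every finite transcript, means of genes, a length limit and the removal of ribosomal protein genes was chosen after. No paired analysis was possible because the deposited columns are comparisons that carry no replicates. For the same reason other pseudocounts, level filters, scalings, test settings, another count model, other list tests and leaving out replicates were not run. At an adjusted p under 0.05 the marked transcripts numbered 616 instead of 1846 and their genes 557 instead of 1501; this follows from the stricter limit. A log2 limit of 1 left both counts as they were, since no marked transcript lay under it, and finite folds alone left 1324 transcripts in 1124 genes. With every finite transcript 7 instead of 11 gene lists passed; with means of genes 12 passed and with transcripts of at least 1000 bases 12. Means of genes gained apoptosis (0.838, adjusted p = 0.000725) and YAP targets (0.56, 0.0398) and lost the epithelial-mesenchymal list (0.125); the length limit gained RNA hosts (0.62, 0.0218). None of the 11 lists reversed in these 3 settings; the lists for which every finite transcript ended the call were the checkpoint, epithelial-mesenchymal, immediate early and ductal lists, and the cause was not tested. The share of genes with a higher peak was 57.2% at a false discovery rate under 0.05, 63.3% at an absolute log2 difference of at least 1 and 57.2% over all peaks. The odds ratio for 3' UTR ran from 2.25 to 2.46 over the 4 alternatives. The difference in input RNA between genes with higher and lower m6A turned to -0.06 (-0.0567, permutation p = 0.548) at an absolute log2 difference of at least 1, fell short of the threshold with every finite transcript (0.0626, p = 0.123), and kept its side at the stricter false discovery rate and with medians; the cause was not tested. Of the 3 marked PHF10 transcripts, 3 had an adjusted p under 0.05 and 1 a finite fold. Depth, which the tables do not give, limits all folds of rarely read transcripts.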

Other observations

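All tests of explanations and of KEGG pathways in this part were chosen after the results were seen. Among 275 KEGG pathways named in the deposited transcript table, 33 had a median gene fold apart from random lists after adjustment. Genes of ribosome biogenesis lay higher with fisetin, with a median log2 fold change of 0.48 over 70 genes (adjusted p = 0.00550), as did the cytosolic DNA-sensing pathway at 0.49 over 35 genes and the NF-kappa B signaling pathway at 0.40 over 61 genes (adjusted p = 0.0145 and 0.0179). Of those lower, ECM-receptor interaction had a median of -0.38 over 52 genes, the Hippo signaling pathway -0.16 over 125, regulation of actin cytoskeleton -0.11 over 154 and focal adhesion -0.12 over 149 (adjusted p = 0.00550, 0.00550, 0.00550 and 0.00750). Tight junction, Adherens junction and Cell adhesion molecules did not pass (adjusted p = 0.190, 0.223 and 0.251). Homologous recombination at 0.51 over 40 genes and Cholesterol metabolism at -0.34 over 25 passed against random lists (adjusted p = 0.0075 and 0.0187). Several other pathways close to the fixed glycolysis and hypoxia, cholesterol, stress and NF-kappaB lists did not pass. These were Glycolysis / Gluconeogenesis at -0.04, HIF-1 signaling at -0.09, Steroid biosynthesis at -0.10, Protein processing in endoplasmic reticulum at 0.14 and TNF signaling at 0.11 (adjusted p = 0.394, 0.0960, 0.460, 0.803 and 0.918). The pathways share genes, and genes are not replicates. Among differential peaks, 0 of 50 pathways differed in direction after adjustment by Fisher's exact test; before adjustment the strongest was Autophagy - animal, with 16 higher and 1 lower genes (p = 0.00851, adjusted p = 0.426).

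The first pattern is that the authors' p tracks the fold closely in the transcript table. The smallest p among the 33066 finite transcripts with a p under 1 and an absolute log2 fold under 1 was 0.22, whereas 594 of 761 peaks with an absolute difference under 0.5 had a p under 0.05. This is consistent with 1 spread shared by all transcripts, rather than a spread measured for each. Whether a fold limit was applied to the calls stays open, since 0 finite transcripts under that fold had a p under 0.05 on which a limit could act. The PHF10 transcript at -1.33 departs from that relation: the smallest p of 2779 others near its fold was 0.09, and the smallest absolute log2 fold of any other finite transcript with a p of 0.00 was 3.12. The 2 PHF10 m6A regions depart likewise, with a p of 0.01 where other regions at their false discovery rates have 0.08 and 0.12, and why these 3 rows stand apart stays open, since no table holds values per library.

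The second pattern is the excess of 3' UTR positions among higher m6A peaks. Coverage shifted along transcripts toward the 3' end would leave 5' UTR peaks less often higher than exon peaks, and within groups of like region length they were more often higher (odds ratio 1.64, 95% interval 1.30 to 2.08). Up to 500 bases 81.5% of 3' UTR, 65.0% of 5' UTR and 52.0% of exon peaks were higher, against 47.8%, 45.5% and 33.7% of longer ones, so the excess lay mostly in short regions. Within groups of like length the odds ratio for 3' UTR was 2.03 (1.71 to 2.42), or 3.10 (2.39 to 4.03) up to 500 bases and 1.42 (1.12 to 1.81) above, which argues against genomic span as the whole cause but not as a part of it. All these lengths are genomic spans that include introns, so the length of a region on the RNA was not tested. A change in RNA level of the same genes is argued against by an odds ratio of 1.98 (1.44 to 2.73) over 655 peaks in genes whose median input log2 fold lay within 0.25 of 0. An effect of fisetin on where m6A lies may remain as a hypothesis, and antibody efficiency or depth of single libraries could not be tested.

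The third pattern is that transcripts of 1 gene were marked in opposite directions, as for CSNK2A1. This occurred in 130 of 251 genes with at least 2 marked transcripts, against 139 with shuffled directions (central 95% range 124 to 154, permutation p = 0.251), so neither reads moved between isoforms nor a change of the whole gene was visible in that count. Among transcripts with an adjusted p under 0.05 the genes in both directions were fewer than shuffled, 16 of 46 against 23.8 (permutation p = 0.029). Marked infinite folds alone gave 9 of 30 against 15.5 (permutation p = 0.0277). Marked finite folds alone were not apart from shuffled, 69 of 144 against 78.8 (permutation p = 0.108). Unmarked transcripts with a p under 1 differed by -0.0691 log2 between genes with only higher and only lower marks (permutation p = 0.129), and by 0.205 (p = 2e-05) when every finite transcript was taken. The first of these differences was not apart from 0, and only the second lay on the side of a change of the whole gene. The answer thus depended on which transcripts were taken. The explanations cannot be told apart, because the tables give no gene totals.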
